A study of Drosophila melanogaster with 6 samples.

How the data were processed

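MeDIP-seq libraries of adult fly heads were compared between 3 lead and 3 control samples, grouped by their titles. Per the submitters' processing notes, reads were trimmed with cutadapt and aligned with Bowtie2 2.1.0 to dm6; the peak caller and its threshold are not given in the sources used here. Per the labels' protocols, DNA was sheared by sonication and part of the ligated DNA was kept as input before immunoprecipitation. The authors called peaks in each library against its own input and did not pool replicates, as the deposited lists show.

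Each deposited list gives a whole-number score per peak whose meaning is not stated. It is the authors' own value and was used only to rank or filter peaks within a list. Lists repeat some peaks over several rows, and each peak was counted once. Coordinates are 1-based. The number of reads per library is unknown here, so differences in depth could not be removed, and they can change how many peaks are called.

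Overlapping peaks were merged into regions (overlap of at least 1 bp), and a library occupied a region if it had a peak there. Gene positions came from a RefSeq table of the same assembly (Release 6, 17807 genes), which gives no strand, exons or sequence. Genes were therefore counted with 1 kb on either side in place of the planned 1 kb upstream, and peak midpoints were put in 3 classes (gene, within 1 kb of a gene, farther) in place of the planned exon and intron classes. The tandem-repeat comparison needs sequence and was not run.

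Group means were compared by exact permutation of the 6 library labels (20 assignments, two-sided), and peak-set similarity by the Jaccard index of covered bases over 10 splits. Adjusted p-values are Benjamini-Hochberg. The 16 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists were compared with 10000 random lists matched on gene length in 20 bins. Named genes are up to 12 per direction by presence in 3 against 0 libraries (then 3 against 1), ranked by score percentile, up to 8 present in all libraries, and up to 4 per list with the largest difference; up to 5 regions are named per direction. Shares carry 95% Wilson intervals, which cover counting error only.

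Alternatives were a stricter score (at least the median of 47), equal numbers of peaks (the 1379 highest by score), the main chromosome arms, leaving out each library, other overlap and merging rules, gene bodies alone, and the replicate number as a block. Leaving out X, counting peaks near either gene end and ranking by score per bp were added after the data were seen. A model in which regions differ in how readily they are called and libraries differ in yield, with no group term, was also added after the data were seen.

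Tests of explanations for the X share of lead replicate 1 were all chosen after it was seen. Of these, 3 (the shift of X regions, its spread along X and the Y regions) were first computed on the scores themselves and then changed to places within the same shared regions of each list, because a score can be compared only within its list. For the Y regions the measure and the bounds that decide the outcome were both changed after the first result had been seen.

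The functions were tested on simulated peak lists over 4538 regions: of 200 planted lead-only regions 67.5% were recovered, where the planted detection rates give 68.6%, and with nothing planted 28 regions were lead-only where the yield model gave 27.9. The simulation has the same form as the yield model, so it checks the code and not the model's match to these libraries. With the planted regions, 151 were lead-only and the yield model gave 46.9, so fitted yields take up part of a group effect. The list test was run on the real peaks. Of 40 random lists of genes (17807 genes), 0 had p below 0.05. The 1 planted list was filled in part from genes with a peak, so its adjusted p of 0.00820 follows from its construction. These lists check the code. They were not matched in gene length to any list tested here, so they do not give its rate of false positives. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.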

Results

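Methylated DNA was profiled in adult heads of wild-type Drosophila melanogaster by MeDIP-seq, in which an antibody against 5-methylcytosine pulls down sheared genomic DNA and the recovered fragments are sequenced beside an input library. The lead group (labelled 800 um) and the control group (labelled 0 um) each held 3 libraries, and all carried the label F3. The lists held 1746, 2414 and 2157 peaks in control replicates 1, 2 and 3, and 3522, 1379 and 2536 peaks in lead replicates 1, 2 and 3. Sequencing depth per library is unknown here, so the absence of a peak does not show that a region was unmethylated. Nor does a peak by itself show methylation, since repeats, a known source of signal in antibody enrichment, were not tested. The labels do not say that replicates came from separate cultures or animals. The p-values of group differences between libraries measure only the spread between these samples, which may be technical. Those of gene lists against random lists measure the spread between genes within these libraries.

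The series asked whether lead exposure altered genome methylation. Lead libraries held 2479 ± 1073 peaks (SD, n = 3) and control libraries 2106 ± 337 (SD, n = 3), a difference of 373.3 peaks that was smaller than the spread among lead libraries (exact permutation test, two-sided, p = 0.6). Peaks covered 906 ± 372 kb in lead and 775 ± 105 kb in control libraries (SD, n = 3; exact p = 0.7). Median peak width was 288 ± 5.03 bp in lead and 290.2 ± 11.5 bp in control libraries (SD, n = 3; exact p = 0.8). With 3 libraries against 3 the smallest two-sided p is 0.1. Without lead replicate 1 both differences turned, to -148 peaks and -45.3 kb, and without lead replicate 2 they were 923 peaks and 326 kb.

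**Figure D1:**
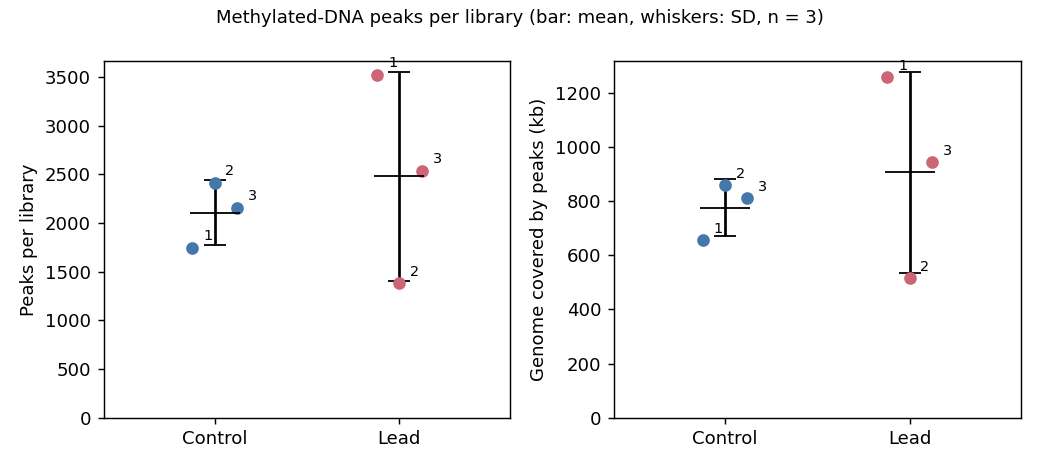
Number of peaks (left) and kilobases covered by peaks (right) in each control and lead library; points are libraries with their replicate number, the bar is the group mean and whiskers are the SD (n = 3). The lead libraries range from 1379 to 3522 peaks, on both sides of all control libraries.

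Libraries of one group did not share more of their covered bases than libraries of different groups. The mean Jaccard index, the shared fraction of the bases covered by either of a pair of libraries, was 0.472 within groups and 0.482 between groups (one-sided exact permutation over 10 splits, p = 0.8; smallest possible p 0.1). Control libraries had a mean index of 0.514 among themselves and lead libraries 0.430. Lead replicates 1 and 2 had the lowest index of the 15 pairs, 0.354. They also covered the most unequal lengths, 1258 and 516 kb, and unequal coverage lowers the highest index a pair can reach. This pair enters the lead mean. Of the peaks of lead replicate 2, 91.8% overlapped a peak of lead replicate 1, and 35.6% did the other way. The difference of -0.00998 turned to 0.000574, 0.0254 and 0.00698 without lead replicates 1, 2 and 3.

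**Figure D2:**
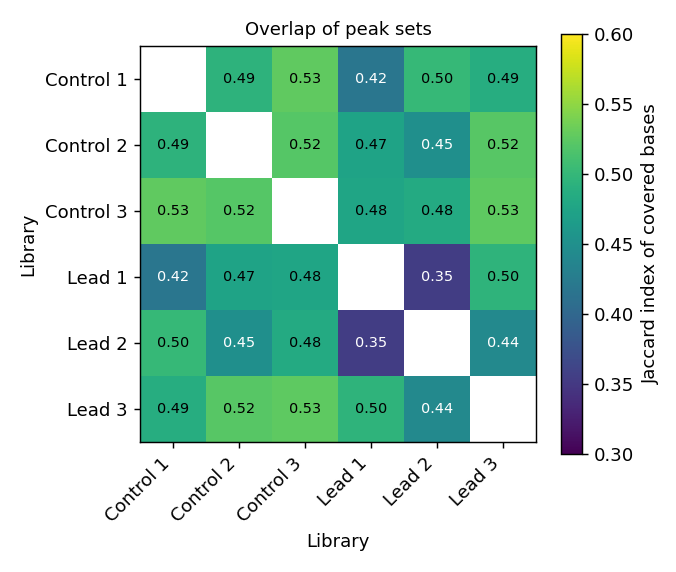
Jaccard index of covered bases for each pair of the 6 libraries, with both axes listing the libraries and colour giving the index. Indices run from 0.354 (lead replicates 1 and 2) to 0.526 (control replicates 1 and 3).

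Merged peaks gave 4538 regions, of which 890 had a peak in all 6 libraries and 1611 in a single library. Peaks were present in all lead and no control libraries at 20 regions. By score rank, the first 5 were on Y at 3006760 to 3007185 (dm6), 15104 bp from FDY; on 3R at 14468269 to 14468559 in cv-c; on 3L at 12476886 to 12477120 in CG10663; on 3L at 17323476 to 17323723 in CG13724; and on 3L at 19019492 to 19019807 in nkd, an antagonist of Wingless signalling. Peaks were present in all control and no lead libraries at 7 regions. The first 5 were on 3R at 27426058 to 27426345 in side, an axon guidance gene; on 3R at 11543113 to 11543390, 164 bp from dpr4; on 3R at 3520121 to 3520397 in Parp1, a poly(ADP-ribose) polymerase; on 2L at 8278333 to 8278618 in Btk, a tyrosine kinase; and on 2L at 2790206 to 2790537 in Syt1, the synaptic vesicle calcium sensor. Counted as whole genes, side and Syt1 had a peak in 3 lead and 3 control libraries, and Parp1 in 2 lead and 3 control libraries. No single region could pass a test, since Fisher's exact p for 3 against 0 is 0.1. The count of 20 was 54 and 48 without control replicates 2 and 3, 213 and 38 without lead replicates 2 and 3, and 8 with equal numbers of peaks per library. The count of 7 was 36, 22 and 18 without control replicates 1, 2 and 3, 44 and 24 without lead replicates 1 and 3, and 19 with equal numbers.

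A peak lay in or within 1 kb of 2173 of 17807 genes in at least 1 library and of 657 genes in all 6. Lead libraries marked 1365 ± 491 genes and control libraries 1217 ± 123 (SD, n = 3; exact p = 0.7). Genes with a peak in all lead and no control libraries numbered 11: cv-c, CG10663, CG13724 and CG13725 (which share a peak), nkd, app, CG14257, CG44774, CG7299, L and CG14435. The app gene encodes a palmitoyltransferase of the Fat pathway, and L (Lobe) acts in eye growth. For app, CG14257 and L the peaks fell in 2 regions each, and none of the 20 lead-only regions lay in or within 1 kb of them. The next by the same rule was foxo, a transcription factor of insulin and stress signalling, with a peak in 3 lead and 1 control libraries. In the other direction dpr4, of the immunoglobulin superfamily, was the 1 gene with a peak in all control and no lead libraries. CG6184, Traf4, Nop60B with snoRNA:Psi18S-1820, Su(z)2, CG31176, Ptip, CG3690, CG34106 with beat-IIIa, and tey had a peak in 3 control and 1 lead libraries, and the lead library was replicate 1 for each. The count of 11 was 2 with equal numbers of peaks, 20 without control replicate 2 or 3, and 78 and 18 without lead replicates 2 and 3. The count of 1 was 14 with equal numbers, 8, 5 and 5 without control replicates 1, 2 and 3, and 19 and 10 without lead replicates 1 and 3.

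Of the 8 genes with a peak in all 6 libraries and the highest score percentiles, 4 lay on the Y chromosome. The 8 were Ppr-Y, kl-5, kl-2 and ORY on Y, Pzl on 3R, and CG2839, lectin-21Ca and lncRNA:CR45369, which share 1 region on 2L. kl-5 and kl-2 encode dynein heavy chains of the sperm axoneme. The lowest percentile of the 6 libraries was 99.9 for Ppr-Y and 98.8 for CG2839. A gene's percentile is that of its best single peak, and Ppr-Y spans 248273 bp. The highest score of each library lay outside genes, on 2R at 1825694 to 1826717, 18352 bp from the nearest gene. Peaks with a score above 10000 numbered 11 to 13 per library and held 75.2% to 88.2% of the summed score.

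Peak midpoints lay in annotated genes for 74.8% ± 1.48 of peaks in lead and 74.4% ± 1.51 in control libraries (SD, n = 3; exact p = 0.7), where genes made up 69.0% of the assembled span. Within 1 kb of a gene lay 2.42% ± 0.346 and 2.56% ± 0.0457 (SD, n = 3; exact p = 0.8), against 7.57% of the span. The in-gene difference of 0.450 points turned to -0.369 without control replicate 2 and -0.308 without lead replicate 1. Arm 2L held a mean of 11.2% of peaks per library against 17.2% of the span, and X held 24.3% against 17.3%. X took 25.2% ± 6.04 of peaks in lead and 23.5% ± 0.999 in control libraries (SD, n = 3; exact p = 1). In lead replicate 1 the X share was 32.1% (95% Wilson interval 30.6 to 33.7, counting error only), while the other 5 libraries lay between 21.6% and 24.5%. Without that library the difference of 1.69 points turned to -1.79. Y held 1.34% ± 0.523 of peaks in lead and 1.35% ± 0.210 in control libraries (SD, n = 3; exact p = 1). Lead replicate 1 had the lowest Y share, 0.738% (95% Wilson interval 0.504 to 1.08), with the other 5 libraries between 1.16% and 1.67%; with equal numbers of peaks it was 1.23% (0.771 to 1.97), against 1.38% to 1.89%.

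**Figure D3:**
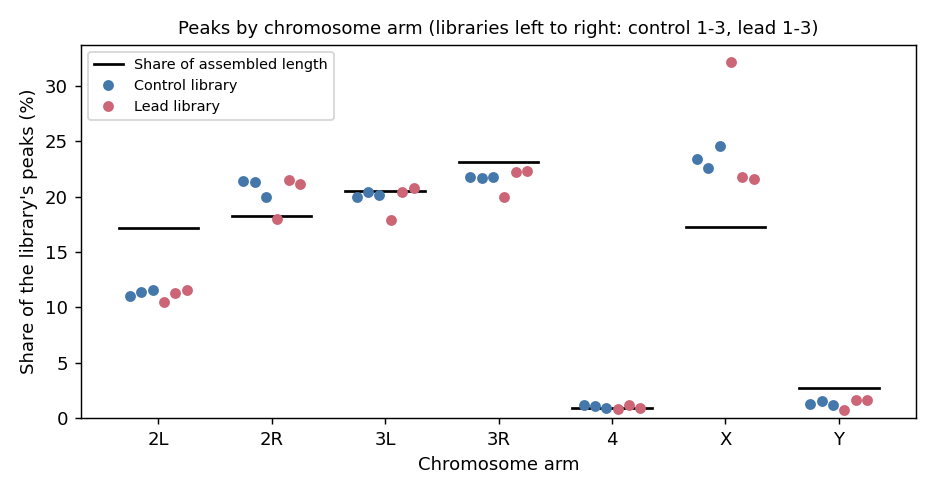
Share of each library's peaks (percent) on each chromosome arm; points are the 6 libraries, control in blue and lead in red, and the black line is the arm's share of the assembled length. On X, lead replicate 1 stands at 32.1% and the other libraries between 21.6% and 24.5%.

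Genes of synapses and memory carried peaks more often than genes of matched length. A mean of 38.2 of 88 members had a peak per library where length-matched random lists gave 28.2, a ratio of 1.35 (10000 random lists, two-sided permutation p = 0.00280, adjusted over 16 lists 0.0448), and 28 members had a peak in all 6 libraries. Of its members, Nlg2, a neuroligin, had a peak in 1 lead and 3 control libraries, Dop1R2, a dopamine receptor, in 2 and 0, 5-HT1A, a serotonin receptor, in 3 and 2, and orb2, a translation regulator needed for long-term memory, in 2 and 1. The adjusted p passed 0.05 in 6 of 13 settings and ranged from 0.00960 to 0.703. It was 0.0512 without control replicate 3, 0.0736 without lead replicate 2 and 0.0608 without lead replicate 3. Its ratio lay between 1.32 and 1.49 in the 13 settings. Members that share a peak were counted separately, and the random lists were not matched for neighbouring genes. The p-value may therefore be too small. Between lead and control libraries, the difference in members with a peak did not pass for any of the 16 lists when set against length-matched lists (adjusted permutation p from 0.921 to 1); the exact test over libraries cannot pass with 3 against 3. No list had a member with a peak in all libraries of one group and none of the other.

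The other 15 lists did not pass the adjusted test against genes of matched length. For the members named by rule, the first number below counts lead and the second control libraries with a peak. Chemosensory receptors had a mean of 3.50 of 238 members with a peak where 8.17 were drawn by chance (permutation p = 0.0266, adjusted 0.213), with Or47a in 2 and 0, Ir87a in 1 and 2, Obp44a in 2 and 3 and Ir93a in 2 and 1. The 238 include an entry without a gene symbol, which had no peak in any library. The ribosomal protein, histone and transfer RNA lists, also matched by name pattern, may hold it too. Metal handling genes had 1.83 of 45 (3.68 by chance), with PMCA and Zip99C in 1 and 0 and ZnT77C, a zinc transporter, in 2 and 1. Oxidative stress genes had 5.67 of 61 (3.69 by chance), with foxo in 3 and 1, Zw, which encodes glucose-6-phosphate dehydrogenase, and DJ-1alpha in 2 and 0, and SelR in 2 and 3. Ion channel genes had 17.7 of 62 (15.7 by chance), with Piezo in 2 and 0, Shal in 3 and 2, KCNQ in 1 and 0 and Best1 in 2 and 1. Axon guidance and adhesion genes had 36.7 of 93 (38.6 by chance), with beat-IIIa in 1 and 3, beat-Ic in 2 and 0, beat-VI in 3 and 1 and Ten-m in 2 and 3. Neural development genes had 24.8 of 86 (21.9 by chance), with tup in 1 and 3, Dfd in 2 and 3, lola in 3 and 2 and oc in 0 and 1. DNA methylation and chromatin genes had 14.7 of 86 (11.2 by chance), with Su(z)2 in 1 and 3, Su(var)2-10 in 1 and 2, chm in 1 and 0 and Parp1 in 2 and 3. Circadian genes had 5.33 of 27 (5.49 by chance), with NPF in 2 and 0, timeout in 2 and 1 and vri in 1 and 0. Eye and photoreceptor genes had 7.33 of 59 (7.67 by chance), with sev in 1 and 0, Gbeta76C in 2 and 1, g in 1 and 2 and so in 3 and 2. Germline genes had 9.67 of 68 (7.30 by chance), with vas and orb in 1 and 0, dj in 2 and 3 and tej in 2 and 1. Glial genes had 2.5 of 31 (5.08 by chance), with htl in 1 and 0, Nrg in 1 and 2 and bnb in 0 and 1. Fat body, muscle and hemocyte genes had 11.5 of 60 (9.30 by chance), with Mef2 in 3 and 1, Mhc in 2 and 3, and Col4a1 and bt in 3 and 2. Ribosomal protein genes had 1 of 86 (2.35 by chance). Replication histones had 3.17 of 112 (3.05 by chance), with His3:CG33866 in 0 and 1. Transfer RNA genes had 3.17 of 296 (4.44 by chance), with tRNA:Pro-CGG-1-1 in 3 and 2, tRNA:Pro-AGG-1-4 in 2 and 1, and tRNA:Met-CAT-1-3 and tRNA:Trp-CCA-2-5 in 1 and 0.

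**Figure D4:**
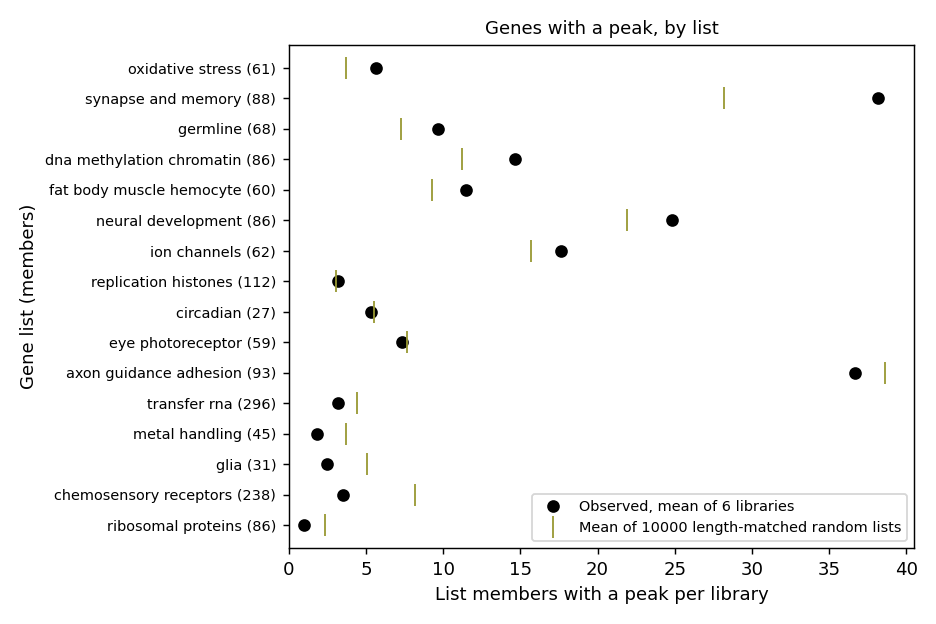
Members of each gene list with a peak per library (horizontal axis, number of genes); black points are means of the 6 libraries and ticks are means of 10000 length-matched random lists, with the number of members in brackets. Synapse and memory genes stand at 38.2 against 28.2.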

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

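Leaving out X, peaks near either gene end and score per bp were chosen after seeing the data. Of 123 alternative values, 77 kept their direction, side of the threshold or count within 1.5 times. These include the values with the replicate block, which could not change. No group difference had p under 0.1, the smallest the exact tests allow, so none could pass. Without lead replicate 2, the differences of 923 peaks, 326 kb and 0.0254 in Jaccard index reached that smallest p of 0.1 (exact permutation). Depth per library is unknown, which limits every count of absent peaks. The tandem-repeat settings and the transcription-start window were not run, since sequence and strand were not used here, and equal numbers give no value for the number of peaks.

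Without each library in turn, differences ranged from -148 to 923 peaks, -45.3 to 326 kb, -0.0359 to 0.0254 in Jaccard index, -0.369 to 1.17 points in genes and -1.79 to 3.47 points on X. Lead-only regions ranged from 27 to 213, control-only regions from 9 to 44, lead-only genes from 13 to 78, and control-only genes from 1 to 19; fewer libraries must then hold or lack a peak, and none of these counts was lower than with all 6. Gene lists past the test ranged from 0 to 1.

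With the stricter score, lead-only and control-only regions numbered 13 and 11, genes 7 and 5, and 0 lists passed. With equal numbers of peaks, regions numbered 8 and 19, genes 2 and 14, 0 lists passed, and the in-gene difference turned to -0.0483 points. The covered difference fell there from 130.7 to 11.4 kb, and the X difference rose from 1.69 to 3.00 points. The difference of 373.3 peaks was 203.7 with the stricter score and 207 without X. Equal numbers by score per bp gave 6 and 27 regions. Gene bodies alone gave 0 control-only genes. Near either gene end there were 4 lead-only genes and 0 lists passed. Without X 0 lists passed too. That setting removed the peaks on X but kept its genes in the lists and random lists, so it does not test autosomal genes alone. The synapse and memory ratio was 1.49 near either gene end, 1.32 without X, 1.38 with the stricter score and 1.40 with equal numbers. Beyond fewer peaks or fewer genes with a peak, the cause was not tested.

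The labels do not say whether the replicate numbers pair the samples. No pairing was seen in the peak lists (correlations of deviations for equal numbers 0.0114, -0.0147 and -0.00577, for unequal numbers -0.0281 to 0.0310). The replicate block cannot change the differences (373.3 peaks, 130.7 kb, -0.00998, 0.450 and 1.69), the 20 and 7 regions or the 11 and 1 genes. Only p-values could change, and for the number of peaks the exact sign-flip p was 0.75. The smallest sign-flip p is 0.25. The gene lists were not run with the block.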

Other observations

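Regions found in a single library were unevenly spread over the libraries and chromosomes. Lead replicate 1 held 869 of the 1611 such regions, and 49.3% of its own lay on X (95% Wilson interval 45.9 to 52.6), against 0 to 22.0% in the other 5 libraries. Lead replicate 2 held 35, with 0 on X.

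Of the tests below, only both tests on the synapse and memory list were written before their results were seen; all others were chosen after. The shift of X regions, its spread along X and the Y test were first computed on scores and then changed to places within lists, and for the Y test the measure and its bounds were changed after the first result had been seen.

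The 20 lead-only and 7 control-only regions make 27. Of the 10 splits of the 6 libraries, 8 gave as many regions, with 129 in the highest other split; for the 12 genes, 7 of 10 splits gave as many, with 63 in the highest other split. With 10 splits no share under 0.05 can be reached. Several splits hold several times the real count, and differing numbers of peaks per library may account for it. Control replicate 2 with lead replicates 1 and 3 alone held 127 regions, where library yields alone gave 124, and 63 genes, where they gave 60.7. Control replicate 3 with lead replicates 1 and 3 alone held 82 regions, where yields gave 87.1. For the real split, yields alone gave 19.4 lead-only regions (95% range 11 to 28) and 6.71 control-only regions (2 to 12). The yields were fitted to these same libraries. An effect of exposure on a smaller number of regions stays open, since the fitted yields can take up part of a group effect.

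The X share of lead replicate 1 was 32.1%. The larger number of peaks in that library is unlikely to account for it, since with 1379 peaks per library its X share was 34.6% and the highest other was 23.6%. A change confined to a small part of X is unlikely too: in all 12 bins of 2 Mb the X regions shared by all libraries stood higher by score in its list, by a median of 2.08 to 22.6 percentile points. The shift was small in the first bin (2.08, 15 regions) and in the last bins (2.89 and 2.87, 12 and 9 regions). Between them it was 9.04 to 22.6. No interval was computed per bin, so a shift at the ends of X is not shown. An effect common to the lead group would need the other lead libraries to be high, and the higher of them was 21.8%, below the lowest control at 22.5%. More X DNA relative to autosomes, as from a larger share of females, is a hypothesis that could not be decided here. The 206 shared X regions shifted up by a median of 10.6 percentile points (bootstrap 95% interval 9.55 to 13), against -3.01 to 0.337 in the other libraries. That shift largely restates the higher X share among the highest scores. It cannot tell more X DNA from other causes of higher X scores in that library. The labels give no sex; the evidence from Y, mixed between measures, follows.

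Fewer Y chromosomes in lead replicate 1 would lower the Y regions there, and the outcome depends on the measure. In the first form of the test, on scores, 11 of the 13 shared Y regions scored below the median of the other libraries, against 4 to 9 for each other library, and 2 scored under 50% of it, against 0. Those 2 were at 322551 to 324151 (score 731, against 4096 to 6053) and 860176 to 860547 (7479, against 18165 to 22317). Scores from different lists have no stated common scale, and lead replicate 1 was lowest of the 6 libraries at 3 regions (those 2 and the one in kl-2, 50195 against 56442 to 58330) and control replicate 2 at 5. The other 10 regions, those in Ppr-Y (121364), kl-5 (110089) and ORY (41358) among them, lay within the range of the other libraries in lead replicate 1. By place among 684 regions outside X, the form adopted afterwards, 4 of 13 stood lower than in every other library, against 0 to 2, which lies between the bounds; place hardly moves among the highest scores. The Y share of peaks was also lowest in this library, 0.738%, and with equal numbers of peaks its interval of 0.771 to 1.97 spans the other libraries' shares. Fewer Y chromosomes therefore stay open.

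The higher number of synapse and memory genes with a peak is unlikely to come from gene length differences left within the bins: with 100 length bins the ratio was 1.40 (permutation p = 0.000800). Matching also on X or autosome, the ratio was 1.35 (permutation p = 0.00540). Neither p was adjusted over the 16 lists. The second was above the permutation p of 0.00280 in the main test, which adjusted to 0.0448. Repeats in these genes, a known source of signal in antibody enrichment, were not tested, so no biological reading is drawn.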
